A study of Homo sapiens with 11 samples.

How the data were processed

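Gene expression was measured on 11 Affymetrix oligonucleotide arrays hybridised with labelled RNA from a human U2OS osteosarcoma line in which doxycycline switches on an introduced estrogen receptor. Per the labels there were 3 untreated samples, 4 samples given tumour necrosis factor (TNF) for 1 h, and 4 samples given 10 nM estradiol (E2) for 18 h and then TNF for 1 h. A group with E2 and no TNF was not analysed here. The labels do not say which samples came from separate cultures, so the p-values measure the spread between these samples, part of which may be technical. The description of TNF sample 2 carries the number of sample 1, and the source name of TNF sample 1 differs from the others. Titles were used for the numbering.

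The deposited values are intensities, the MAS5 signal of each probe set on a linear scale, made by the authors with Microarray Suite under its default parameters, per the labels. The 2% trimmed mean of the deposited signal was 250.1 on all 11 arrays, so the authors had scaled the arrays to a common level. Detection calls and the authors' array-to-array comparison files were not used here. The series description names the U95Av2 array, whereas the probe set identifiers are those of the U133 array, set A, and the latter was taken as the array type. The file held 22283 probe sets, of which 68 were control probe sets and were left out of the tests. Of all probe sets, 19071 had 1 gene symbol in the platform annotation, 1043 had several and 2169 had none or were not listed. Symbols were checked through Entrez identifiers against the RefSeq genes of assembly GRCh38.p14, where 19059 of the 19071 matched and 0 symbols changed. Probe sets with several symbols or none were tested and counted but not named. No coordinates were used.

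Each array was scaled to the same trimmed mean, which moved the values very little, and 12.5 (5% of the trimmed mean) was added before taking log2. Fold changes are therefore on the log2(signal + 12.5) scale, which understates changes of dim genes. Probe sets were kept where the signal exceeded 50.0 (20% of the trimmed mean) on at least 3 arrays, which left 16283 probe sets and 9559 named genes. Where all arrays of a group lay at or below that level the group is called dim, and the fold against it is given as a lower bound. The brightest probe set stood for a gene with several, and among the 218 genes named by the rule below 0 had another kept probe set that passed in the opposite direction. Arrays carry no read depth, and their number limits the precision.

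All 11 arrays entered 1 fit with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend of variance on signal, 2-sided), with no replicate block. Adjusted p is limma's p after Benjamini-Hochberg adjustment over the probe sets kept, and a probe set passed below 0.05. A TNF-induced gene had a log2 fold change of at least 1.2, the study's size threshold, and passed in TNF against untreated. The mean log2 signal over these genes was compared between 4 TNF and 4 E2 and TNF arrays by an exact 2-sided permutation test of 70 arrangements. Gene lists, 17 in number, were tested in each of 3 contrasts with camera at a preset correlation of 0.01, adjusted over all lists and contrasts. The same lists were tested with an estimated correlation and with fry, which asks whether a list's genes move 1 way on balance and does not compare them with other genes. These tests, the lists, the alternatives and the naming rule were fixed before the data were examined, apart from those named below as chosen later.

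The naming rule took, per contrast, the 10 genes with the largest fold each way among those that passed with no overlap between the arrays of the groups, up to 30 TNF-induced genes, the list members that passed with up to 4 bright examples per list, and a few genes fixed by name (ESR1, ESR2, TNFAIP3, NFKBIA, CXCL8, CCL2, IL6, TNF and ICAM1). The fit was tested on simulated data for the contrast of E2 and TNF against TNF, with 200 of 16283 probe sets changed. The signal filter, applied again to the simulated signals, left 15755. Among changed probe sets that passed this filter, it recovered 30.2% of those changed by 0.5 on the log2 scale, 77.0% at 1 and 96.9% at 2. Changed probe sets lost to the filter are not counted in these shares. There were 3 false calls among 132. A simulated shift of 0.5 in 1 list was called and 0 other lists were.

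Alternatives covered quantile normalization, no rescaling, median centring, pseudocounts of 1% and 20% of the trimmed mean, no filter and a filter at 50% of it, the sample number as a replicate block, fits on the compared groups alone, other variance priors, array weights, each array left out in turn, adjusted p below 0.01, the study's own thresholds, the mean of a gene's probe sets, and other selections of the TNF-induced genes. A further alternative, in which samples 1 and 2 of TNF and of E2 and TNF were averaged, was chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.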

Results

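The 11 arrays read transcripts in U2OS cells, a human osteosarcoma line, carrying a doxycycline-induced receptor that the labels give as estrogen receptor β. These are called cells labelled U2OS-ERβ. There were 3 untreated, 4 TNF, and 4 E2 and TNF arrays. Between 64.9% and 68.0% of probe sets exceeded a signal of 50.0 on each array, and the median signal ran from 95.6 to 107. The ratio of 3′ to 5′ probe sets, a sign of RNA quality, lay between 0.767 and 0.835 for GAPDH and between 0.942 and 1.08 for β-actin. Values below are group means ± SD of the signal (n = 3 untreated, n = 4 TNF, n = 4 E2 and TNF) or log2 fold changes ± SE.

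In the cells labelled U2OS-ERβ, of 9 probe sets for ESR1, which encodes estrogen receptor α, 5 were bright on all 11 arrays, with signals from 1564 to 14191, and 4 stayed at 116 or below. All 5 probe sets for ESR2, which encodes estrogen receptor β, lay between 1.12 and 119, and 3 of them passed the signal filter. The positions of these probe sets relative to the introduced cDNA were not used here, so a probe set outside it would check nothing. Directions drawn below from E2 are those of arrays labelled U2OS-ERβ, whatever receptor the cells carried.

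**Figure D1:**
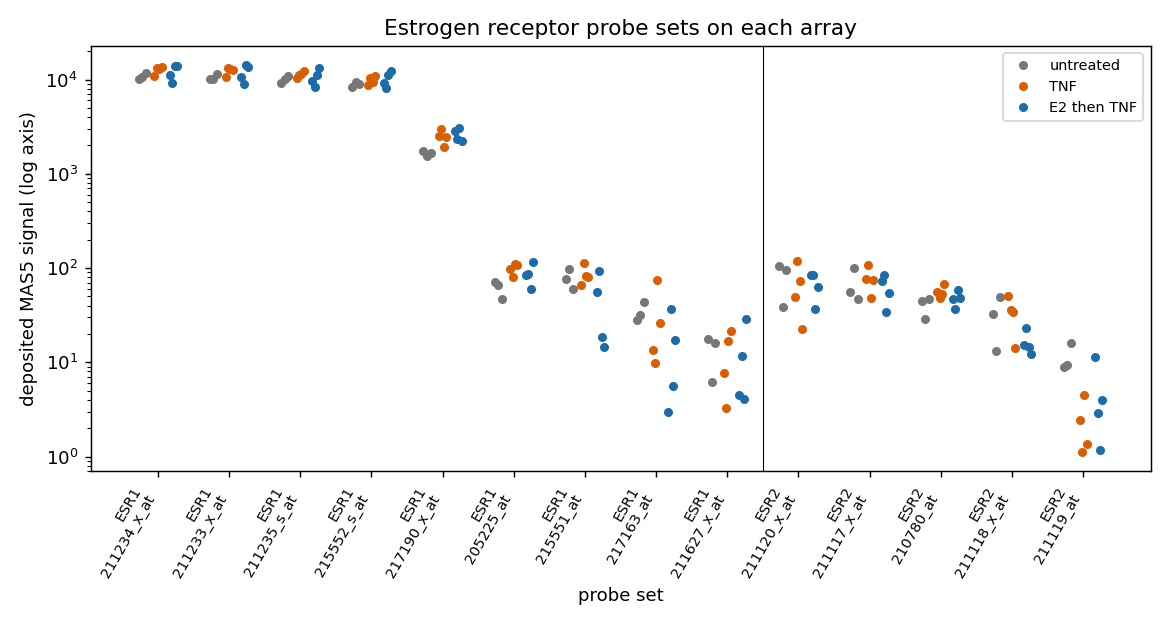
Deposited signal (log axis) of 9 ESR1 and 5 ESR2 probe sets, with a point for each of 11 arrays coloured by group. The 5 bright ESR1 probe sets lie at 1564 or above and all 5 ESR2 probe sets at 119 or below.

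The first comparison asked which transcripts 1 h of TNF changed. The neutrophil chemokine CXCL8 went from 821 ± 159 to 7414 ± 1283 (log2 change 3.16 ± 0.13, adjusted p = 1.34e-10). CXCL3, dim in untreated arrays, rose at least 12.7-fold to 790 ± 114. TNFAIP3, a deubiquitinase that restrains NF-κB, rose by 2.74 ± 0.08 (adjusted p = 2.47e-12), and the inhibitor gene NFKBIA by 2.27 ± 0.11 (adjusted p = 4.17e-10). CCL4, PTX3, TNF itself, the transcription factor IRF1, LTB and EDN1 rose by 3.31, 2.83, 2.68, 2.67, 2.55 and 2.37, and the lymphocyte activation marker CD69 at least 3.12-fold. Fewer genes fell. The growth factor gene FGF9 had a log2 change of -1.08 ± 0.12 (adjusted p = 3.19e-05), TENT5A of -1.01 ± 0.14, TXNIP, whose protein binds thioredoxin, of -0.96 ± 0.08, and the transcription factor SOX9 of -0.73 ± 0.07. The kinase gene SGK1 fell by 0.83 ± 0.15 (adjusted p = 0.00664), a call lost without untreated replicate 1 (adjusted p = 0.0505).

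In all, 169 of 16283 probe sets passed, 135 higher and 34 lower with TNF, and among named genes 91 rose and 23 fell. Over all 9559 named genes, 1084 (11.3%) had no overlap between the arrays of the groups, a separation chance gives to 5.71%. The adhesion gene ICAM1 did not pass, with 132 ± 29.6 untreated and 155 ± 36.8 with TNF.

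Of 21 measured cytokines and chemokines 12 rose and 0 fell (13 and 0 adjusted over the list alone; camera adjusted p = 6.64e-32). Of 20 genes for NF-κB subunits and feedback 10 rose and 0 fell (11 and 0 adjusted over the list alone; camera adjusted p = 3.40e-26), among them the subunit gene NFKB1 at 1.17 ± 0.20 and TNFAIP2 at 1.15 ± 0.14. Of 26 immediate early factors 9 rose, with JUNB at 1.41 ± 0.09 and MAFF at 1.18 ± 0.09, and 1, ID1, fell (13 and 4 adjusted over the list alone; camera adjusted p = 6.27e-08). The ID1 call was lost without TNF replicate 2 (adjusted p = 0.0675) or 3 (0.0590) or untreated replicate 2 (0.103) or 3 (0.0691). The list named matrix remodelling and coagulation proteases gave 4 higher of 20 (8 adjusted over the list alone; camera adjusted p = 4.03e-10), namely F3, MMP13, PTX3 and TNFAIP6. Below it goes by matrix and coagulation proteases or matrix proteases, but it also holds genes that encode no protease, F3, PTX3 and TNFAIP6 among them. Adhesion and immune surface molecules gave 3 higher of 22 (3 adjusted over the list alone; camera adjusted p = 1.47e-06), namely CD69, IFNGR2 and TNFRSF9. In the osteoblast and bone matrix list BMP2 rose by 1.25 ± 0.10 (1 higher of 23, 3 adjusted over the list alone; camera adjusted p = 4.80e-04). Of 44 cell cycle genes CDKN1B, a cyclin-dependent kinase inhibitor, fell by 0.58 ± 0.08 (1 adjusted over the list alone), and the list was called lower (camera adjusted p = 7.47e-04). Feedback inhibitors of MAPK signalling and RNA decay gave 4 higher and 1 lower of 22 (7 and 1 adjusted over the list alone; camera adjusted p = 0.00259), a call not kept with the estimated correlation (adjusted p = 0.0838). The other 7 calls held with it. Other splits of the arrays also called up to 10 lists here, so the number of lists called cannot be set apart from chance. Those splits mix TNF and untreated arrays, so they are no reference without a TNF effect, and they do not bear on single lists.

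**Figure D2:**
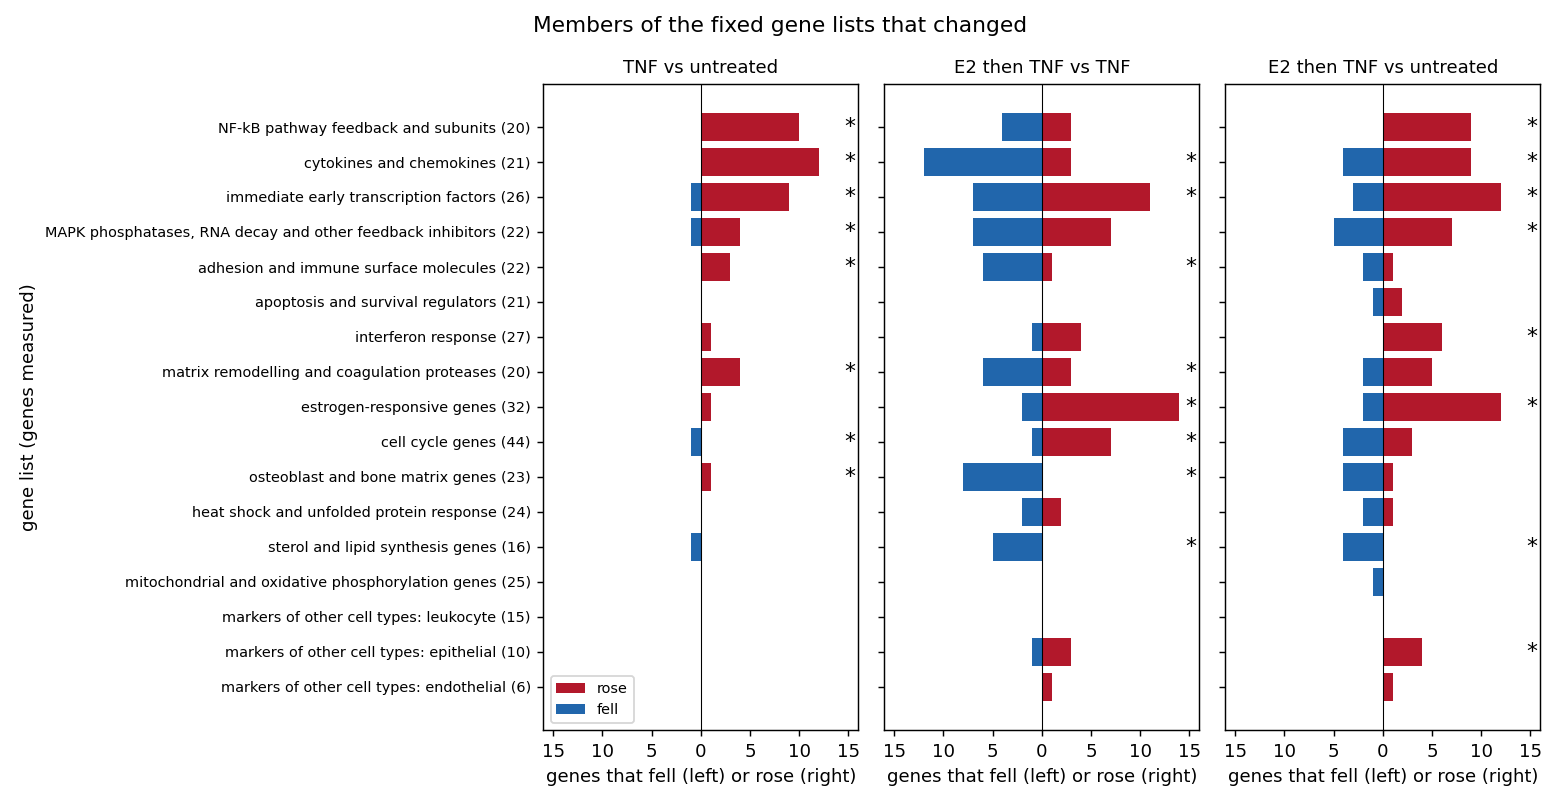
Number of genes of each fixed list that rose (right) or fell (left) in each contrast, with the number measured in brackets and an asterisk where camera called the list. Of 21 cytokines and chemokines, 12 rose with TNF, and 12 were lower and 3 higher in E2 and TNF than in TNF arrays.

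The second comparison, the subject of the series title, asked what E2 before TNF did to genes that TNF induced. By the size and p thresholds 33 genes were TNF-induced, and 25 of them were lower in E2 and TNF than in TNF arrays, 3 were higher and 5 did not pass (27 lower and 4 higher adjusted over the list alone). The chemokine CCL2 fell from 1775 ± 89.1 to 241 ± 45.0 (log2 change -2.83 ± 0.12, adjusted p = 1.97e-10), CCL20 from 4354 ± 411 to 845 ± 91.4, and the cytokine IL6 from 859 ± 44.1 to 157 ± 54.2. These 3 ended below their untreated levels of 400.0, 1269 and 231. For IL6 that last difference (adjusted p = 0.0473) was lost in 10 of the 11 fits that left out an array, all but the fit without E2 and TNF replicate 3, with adjusted p from 0.0525 to 0.166. CXCL8 was lower by -1.31 ± 0.12, TNFAIP3 by -1.60 ± 0.07 and TNF by -1.30 ± 0.15, yet all 3 stayed above untreated, as did 20 of the 33 genes. NFKBIA, at 6228 ± 460 and 5771 ± 758, did not pass (adjusted p = 0.517), and neither did NFKBIE, MMP12, TRAF1 (adjusted p = 0.0520) or NDRG2 (adjusted p = 0.0720). TRAF1 passed as higher without TNF replicate 4 (0.0341), untreated replicate 1 (0.0289) or 2 (0.0328), and NDRG2 as lower without E2 and TNF replicate 3 (0.0499), untreated replicate 1 (0.0438) or 3 (0.00748). The higher genes were CD83, a surface protein of activated dendritic cells (1.71 ± 0.09, adjusted p = 9.09e-10), JUNB (0.66 ± 0.08) and F3, the tissue factor that starts coagulation (1.51 ± 0.22). For TNFRSF9 the other kept probe set did not share the call with TNF or with E2, and for NDRG2 it did not share the call with TNF. For CXCL8, TNFAIP3, TNFAIP6, INHBA and BMP2 the other kept probe set shared both calls.

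Over the 33 genes the median difference was -1.30 on the log2 scale, and a median of 41.4% of the log2 change with TNF was kept, or 25.4% of the rise in signal. The mean log2 signal over these genes was 9.38 ± 0.02 (SD, n = 4) in TNF and 8.25 ± 0.06 (SD, n = 4) in E2 and TNF arrays (exact permutation p = 0.0286, the smallest that 70 arrangements give). The result depends on how the genes are chosen. Genes chosen on the mean of TNF and E2 and TNF arrays against untreated (48, of which 16 are among the 33) had a median of 1.42, with 11 lower and 32 higher, and genes chosen on the E2 and TNF arrays (166, 9 shared) had a median of 1.49, with 4 lower and 147 higher. Both choices admit genes raised with E2 that TNF alone did not raise: 23 of the 48 and 19 of the 166 passed higher in TNF against untreated. Where 2 TNF arrays chose the genes and the other 2 were compared, the mean of 6 medians was -1.21, with p = 0.0667 by exact permutation in each split, the smallest possible.

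**Figure D3:**
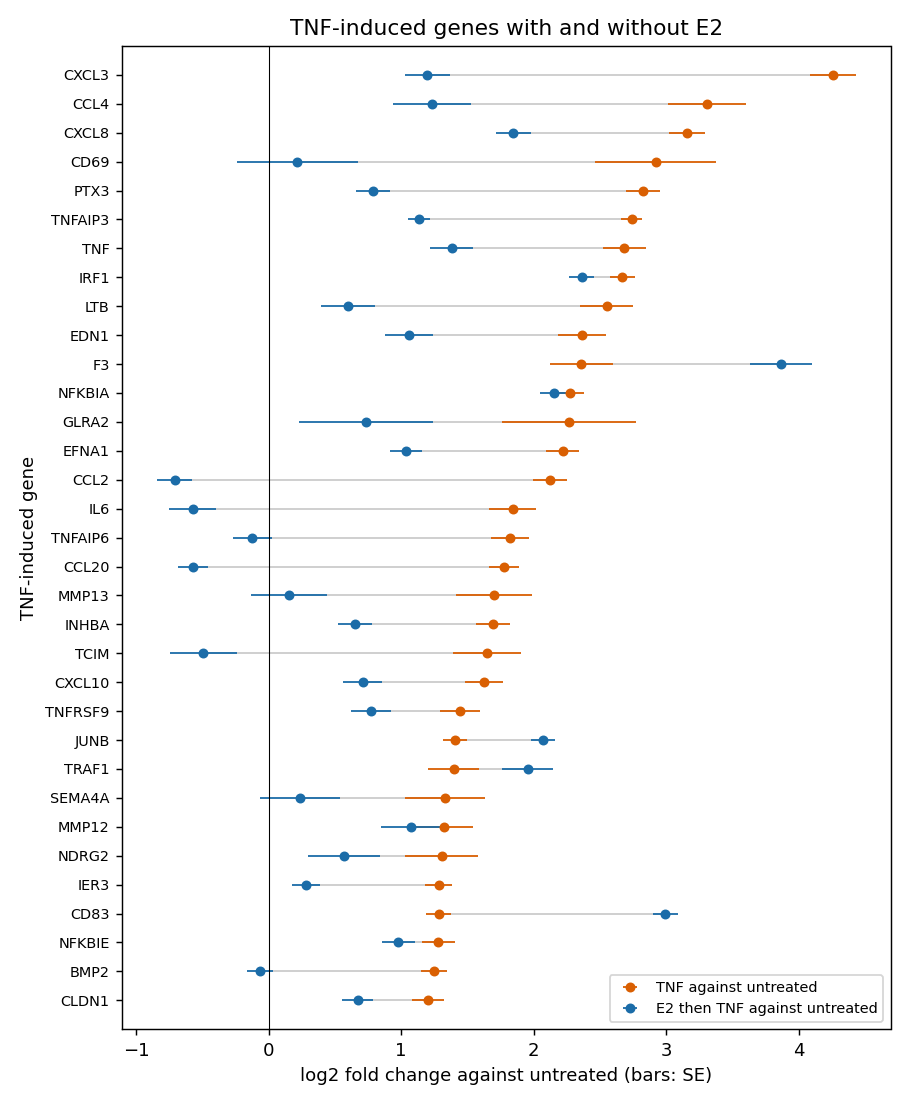
Log2 fold change against untreated (bars, SE) of the 33 TNF-induced genes in TNF arrays (orange) and E2 and TNF arrays (blue). Blue points lie left of orange for 29 of the 33 genes, and those of CCL2, CCL20, IL6, TCIM, TNFAIP6 and BMP2 lie below 0. The last 3 did not pass against untreated (adjusted p = 0.268, 0.694 and 0.761).

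Over all probe sets, those of the TNF-induced genes included, 1975 passed between E2 and TNF and TNF arrays, 1116 higher and 859 lower, and 707 named genes rose and 545 fell. Of all 9559 genes 1742 (18.2%) had no overlap between the groups, which chance gives to 2.86%. LORICRIN, a protein of the epidermal envelope, rose by 4.55 ± 0.30 to 944 ± 191 (adjusted p = 2.07e-08), and RBP4, the plasma retinol carrier, by 4.00 ± 0.29. NLRP3, the inflammasome sensor, was dim without E2 and rose at least 5.92-fold to 359 ± 28.9. KRT19, TH, NEFH and CLIC3 were likewise dim without E2 and rose at least 3.22-fold, 3.11-fold, 3.87-fold and 2.53-fold. The complement gene C3 rose by 3.36 ± 0.20, FOS by 3.32 ± 0.27, PDK4 by 2.98 ± 0.28, SGK1 by 2.92 ± 0.14 and IL17RB by 2.87 ± 0.12. Among genes that fell, TNFRSF11B, which encodes the bone-protecting decoy receptor osteoprotegerin, went at least 2.79-fold down from 167 ± 52.9, and the growth arrest gene GAS1 went from 329 ± 45.3 to 46.9 ± 29.3. CXCL3 changed by -3.06 ± 0.16, CCL4 by -2.08 ± 0.27 and PTX3 by -2.04 ± 0.12, and CD69 and TCIM fell at least 3.12-fold and 2.71-fold.

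Of 32 estrogen-responsive genes 14 rose and 2 fell (14 and 3 adjusted over the list alone; camera adjusted p = 1.10e-06). The growth factor gene TGFA rose by 2.63 ± 0.13, IGFBP4 by 2.11 ± 0.13, CA12 by 1.83 ± 0.15 and the cyclin gene CCND1 by 0.97 ± 0.13, while CXCL12 fell by 0.82 ± 0.13 and CTSB by 0.39 ± 0.07. Epithelial markers, which share KRT19 with that list, gave 3 higher and 1 lower of 10 (3 and 2 adjusted over the list alone). Camera did not call them (adjusted p = 0.292), though fry did (adjusted p = 4.72e-04). Of 21 cytokines and chemokines 12 fell and 3 rose (12 and 3 adjusted over the list alone; camera adjusted p = 7.85e-08), the 3 being IL11, CSF1 and LIF. NF-κB subunits and feedback genes went both ways, with 3 higher and 4 lower of 20 (5 and 5 adjusted over the list alone), and the list was not called (camera adjusted p = 0.941). Of 26 immediate early factors 11 rose, FOS, FOSL1, ID3 and HES1 among them, and 7 fell, with CEBPD at -1.65 ± 0.11 and MYC at -1.01 ± 0.14 (12 and 7 adjusted over the list alone; camera adjusted p = 0.0176). This call was lost with the estimated correlation (adjusted p = 0.221) and without E2 and TNF replicate 3 (adjusted p = 0.0637), and with a stricter signal filter, at 50% of the trimmed mean (adjusted p = 0.0579).

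Adhesion and immune surface molecules gave 6 lower and 1 higher of 22 (6 and 1 adjusted over the list alone; camera adjusted p = 0.00479), with CD58 at -0.79 ± 0.09. Of 23 osteoblast and bone matrix genes 8 fell and 0 rose (10 and 1 adjusted over the list alone; camera adjusted p = 0.00199), including POSTN at -1.23 ± 0.11, BMP2 at -1.31 ± 0.09 and LUM at -0.85 ± 0.13. Of 16 sterol and lipid synthesis genes 5 fell and 0 rose (5 and 0 adjusted over the list alone; camera adjusted p = 0.00392), including HMGCS1 at -0.79 ± 0.14 and SCD at -0.75 ± 0.08, and this call was lost with the estimated correlation (adjusted p = 0.126). Matrix and coagulation proteases gave 6 lower and 3 higher of 20 (9 and 3 adjusted over the list alone; camera adjusted p = 0.0338), a call lost with the estimated correlation (adjusted p = 0.102) and without TNF replicate 3 (0.0517), TNF replicate 4 (0.0569) or E2 and TNF replicate 3 (0.0536). It was also lost with quantile normalization (adjusted p = 0.0581), no filter (0.0559), the stricter filter (0.0939) or averaged probe sets (0.0825). Of 44 cell cycle genes 7 rose and CDK4 fell (10 and 2 adjusted over the list alone; camera adjusted p = 0.00689), with CCNE1 at 0.52 ± 0.08 and RRM2 at 0.60 ± 0.09. Feedback inhibitors went both ways, 7 higher and 7 lower of 22 (9 and 7 adjusted over the list alone), and were not called (camera adjusted p = 0.646). In that list ZFP36, which targets AU-rich mRNAs for decay, rose by 1.98 ± 0.08, while BTG1 changed by -1.28 ± 0.07 and SPRY2 by -1.09 ± 0.11.

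The third comparison set both agents against none. LORICRIN (4.76 ± 0.33, adjusted p = 4.17e-08), C3 (3.92 ± 0.21), F3 (at least 5.70-fold), NLRP3 (at least 5.92-fold), PDK4 (at least 7.48-fold) and IL17RB (3.06 ± 0.13) rose. GAS1 fell by 3.18 ± 0.30, TXNIP by 1.93 ± 0.08, ENC1 by 1.86 ± 0.08, DIO2 by 1.65 ± 0.15, ADAMTS1 by 1.55 ± 0.19 and RIN2 by 1.53 ± 0.16. In all 1853 probe sets passed, 1036 higher and 817 lower, and 639 named genes rose and 512 fell. Of all 9559 genes 2209 (23.1%) had no overlap between the groups, which chance gives to 5.71%.

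NF-κB subunits and feedback genes gave 9 higher and 0 lower of 20 (10 and 0 adjusted over the list alone; camera adjusted p = 1.73e-12), and cytokines and chemokines 9 higher and 4 lower of 21 (10 and 4 adjusted over the list alone; camera adjusted p = 0.00692). Without the signal filter the cytokine call was lost (adjusted p = 0.0746) and the list median turned from 0.04 to -0.05. With each array left out in turn the call was kept, but that median ran from 0.026 to 0.44. Immediate early factors gave 12 higher and 3 lower of 26 (13 and 6 adjusted over the list alone; camera adjusted p = 2.13e-06), and estrogen-responsive genes 12 higher and 2 lower of 32 (13 and 3 adjusted over the list alone; camera adjusted p = 2.13e-06). Of 27 interferon response genes 6 rose and 0 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.00767), including IRF1 at 2.36 ± 0.09, ISG20 at 2.29 ± 0.13 and OASL at 1.21 ± 0.14. Sterol and lipid synthesis genes gave 4 lower of 16 (8 adjusted over the list alone; camera adjusted p = 1.02e-04), with INSIG1 at -1.12 ± 0.09, and were lost with the estimated correlation (adjusted p = 0.0517). Feedback inhibitors gave 7 higher and 5 lower of 22 (9 and 5 adjusted over the list alone; camera adjusted p = 0.0387), lost with the estimated correlation (adjusted p = 0.214) and without E2 and TNF replicate 1 (0.0667), 2 (0.0859) or 3 (0.112). It was also lost with no filter (adjusted p = 0.0626), the stricter filter (0.103), averaged probe sets (0.113) or the sample number as a replicate block (0.0503). Epithelial markers gave 4 higher of 10 (4 adjusted over the list alone; camera adjusted p = 0.0338), namely ELF3, JUP, KRT18 and KRT19. That call was lost with the estimated correlation (adjusted p = 0.101) and without E2 and TNF replicate 1 (0.0552) or 3 (0.0599), with the replicate block (0.0529), and with no filter (0.0897), where the list median turned from 0.12 to -0.03. JUP was lost without untreated replicate 3 (0.0518), and KRT18 without E2 and TNF replicate 2 (0.0622), 3 (0.0886) or 4 (0.0877) or untreated replicate 1 (0.166) or 2 (0.127). Leukocyte markers gave 0 of 15 higher or lower in each contrast. Of 6 endothelial markers VWF rose, at least 2.21-fold (1 higher adjusted over the list alone; camera adjusted p = 0.313), and the list was not called.

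Genes higher with TNF and lower with E2 numbered 46, against 5.19 for independent lists. Simulated unchanged groups gave 0 on average, which follows from call lists that are almost empty without effects and so measures no excess. Both comparisons use the same TNF arrays, so part of the excess may come from them. With the TNF arrays split between the comparisons the mean number was 33.5, against 2.04 for independent lists of the same split. Genes higher in both numbered 16, against 6.73 for independent lists and 0 simulated, and 9.67 with split arrays, against 3.60 for independent lists.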

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

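The tests of a common share, of both receptor explanations and of AU-rich transcripts were chosen only after the results were seen. The split of the TNF arrays was planned, but the bound that decided it was set after its values were seen.

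Of 450 groups of 4 arrays tested, 18 (4.00%) held an array far from the other 3, about the 1 in 20 that chance gives, and 7 of these lay on TNF array 4. On TNF array 4 the signal was low for ATP5F1B (3691.59), CDKN1B (546.05), CISH (41.46) and CXCL5 (92.29), and high for COX6C (4318.34), KLF2 (99.11) and KRT19 (4.86). TNF array 3 was high for EDN1 (400.88), EFNA1 (1108.15) and IFNGR2 (1287.52) and low for JUN (1893.59). TNF array 2 was low for CD58 (538.74) and CX3CL1 (49.54) and high for TH (7.98). Of the E2 and TNF arrays, array 1 was high for CD40 (722.66), array 3 high for TIMP1 (6784.45), and array 4 low for INSIG1 (353.05) and NFKB2 (433.38). KRT19 and TH were dim in all TNF arrays, so these gaps lie among low signals. No explanation was tested for single arrays.

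Each count was set against the 35 splits of the arrays compared. Only the true split reached the 169 probe sets changed by TNF (highest other 2). The same held for the 1975 between E2 and TNF and TNF arrays (highest other 0) and the 1853 between E2 and TNF and untreated arrays (highest other 133). It held for the 33 TNF-induced genes (highest other 1) and the 25 lower with E2 (highest other 0). The 8 lists called between E2 and TNF and TNF arrays (highest other 6) and the 8 between E2 and TNF and untreated arrays (highest other 7) were also reached by the true split alone, by a small margin. For all of these 1 of 35 is the smallest share possible, and it holds only if the samples are independent. Chance cannot be excluded in this way for the number of lists called with TNF against untreated, 8, since 4 of 35 splits called as many (highest other 10). All splits but the true one mix arrays of both groups, which widens the spread within groups. They are therefore no reference without an effect for any of these counts.

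The first pattern weighed was that TNF-induced genes were lower with E2. Genes picked for being high by chance in the TNF arrays would fall elsewhere, yet with 2 TNF arrays choosing the genes and the other 2 compared, the mean median was -1.21, and each of 6 splits lay at -1.08 or below. The test planned for this, on genes selected by the mean of both TNF groups, gave 1.42, above what either outcome foresaw, because that selection admits genes raised with E2, and so it did not bear on chance selection. Scaling of the arrays was argued against, since the highest median under 3 other scalings was -1.30. Of these, no rescaling was no separate check, as the authors had already scaled the arrays. The median difference over all probe sets kept was -0.05, small beside -1.30. A weaker TNF stimulus lowering each gene by a common share of its log2 change was also weighed. From the median loss of 58.6%, 20 of 33 genes departed, 9 keeping more and 11 less. A gene that E2 moves without TNF would depart too, since the untreated arrays had no E2. The departures therefore do not decide on a common share. A weaker stimulus stays open, whether it acts equally or unequally on genes, and the unequal case was not tested. An effect of E2 on TNF-induced transcription or on mRNA decay may account for the pattern and stays a hypothesis, since a group with E2 alone was not analysed here.

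The second pattern was that 5 of 9 ESR1 probe sets lay at 1564 or above and all 5 ESR2 probe sets at 119 or below in cells labelled U2OS-ERβ. On 11 of 11 arrays the brightest ESR1 probe set exceeded 50 times the brightest ESR2 probe set, but this decides nothing, since levels of different probe sets share no scale and the criterion was set after the signals were seen. The highest ESR2 signal was 118.744, which decides nothing for the same reason. Within each array, the 5 bright ESR1 probe sets ranked at percentile 95.9 of signal or above, and no ESR2 probe set ranked above 53.4. Reading of estrogen receptor β transcripts by ESR1 probe sets would have to raise all 5 that far. These tests do not settle between that reading and an estrogen receptor α cDNA, because the probe positions relative to the cDNA were not used here.

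The third pattern was that E2 lowered some TNF-induced genes and not others while ZFP36, which promotes decay of AU-rich mRNAs, rose by 1.98. Faster decay through ZFP36 predicts lower AU-rich transcripts outside the induced set too, but 14 measured there, from a list written after the values were seen, had a median of -0.05 (-0.0471), with 5 higher and 3 lower. A comparison of listed with other induced genes was also made, but is void, since that list was written with their values in view. The transcripts outside the induced set go both ways, so faster decay and other causes cannot be told apart, and decay may still act on the induced genes alone.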

How the results depend on the processing

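The fit with samples 1 and 2 averaged was chosen only after the results were seen. On the third principal component of the arrays (10.6% of the variance), samples 1 and 2 lay close together in TNF (0.693 and 4.68) and in E2 and TNF (1.80 and -1.21). Samples 3 and 4 lay apart there (36.1 and -16.5 in TNF, 15.7 and -17.2 in E2 and TNF). Whether samples 1 and 2 share a culture is not stated in the labels. The averaged fit gave a median of -1.29 over 31 TNF-induced genes, 22 of them lower (p = 0.1 by exact permutation, the smallest possible with 3 against 3). With it 127, 1451 and 1645 probe sets passed in TNF against untreated, E2 and TNF against TNF, and E2 and TNF against untreated. Values below are counts, or medians in log2 of a list, and the cause of a change was not tested unless given. Genes selected on the mean of both TNF groups reversed the median to 1.42 with 11 lower, and those selected on the E2 and TNF arrays to 1.49 with 4 lower. Both admit genes raised with E2. The second selection favours genes high in the E2 and TNF arrays by construction. The first does not, as simulations of it without an E2 effect gave medians from -0.045 to 0.080. Split TNF arrays gave -1.21 (p = 0.0667 by exact permutation, the smallest possible). An adjusted p below 0.01 left 100, 1208 and 1073 probe sets in TNF against untreated, E2 and TNF against TNF, and E2 and TNF against untreated, with 84.0%, 65.7% and 66.5% higher. The study's thresholds gave 108, 359 and 385, with 84.3%, 78.0% and 82.9% higher, and 56 TNF-induced genes. Without a variance trend TNF changed 105.

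Lists called fell to 5 without a filter (E2 and TNF against untreated), and to 5 and 5 with the estimated correlation (E2 and TNF against TNF, and against untreated). In E2 and TNF against TNF, matrix proteases were no longer called with quantile normalization (-0.30), no filter (-0.25), the stricter filter (-0.30), the stricter p (-0.30), averaged probe sets (-0.25) or the estimated correlation (-0.30). Immediate early factors were not called with the stricter filter (0.18), the stricter p (0.18) or the estimated correlation (0.18), nor sterol genes with that correlation (-0.17). In E2 and TNF against untreated, feedback inhibitors were not called with no filter (0.19), the stricter filter (0.28), the stricter p (0.40), averaged probe sets (0.40) or the estimated correlation (0.40). Epithelial markers were not called with no filter (-0.034), the stricter p (0.12) or the estimated correlation (0.12), cytokines with no filter (-0.047), nor sterol genes with the estimated correlation (-0.28). In TNF against untreated, feedback inhibitors were not called with that correlation (0.084).

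Lists gained were, in TNF against untreated, endothelial markers with no filter (0.18), sterol genes with averaged probe sets (-0.10), and with fry interferon genes (0.034) and epithelial markers (0.0026). With each array left out in turn, the median of epithelial markers there ran from -0.015 to 0.081. In E2 and TNF against TNF fry added interferon genes (0.020) and epithelial markers (0.12), whose medians ran from -0.011 to 0.063 and from -0.036 to 0.23 with each array left out. In E2 and TNF against untreated, matrix proteases came in with the stricter filter (0.084) and fry (-0.031), mitochondrial genes with array weights (-0.10) and fry (-0.10), and osteoblast genes with fry (-0.068).

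Same-numbered samples correlated between -0.0014 and 0.0657 in their deviations over 10 pairs. The mean was 0.033, against -0.011 for samples of other numbers. Of 11 arrays 8 correlated best with their own number, which points to a weak sharing by number, though no test of it was made. The main fit and the splits of the arrays take no account of such sharing. The replicate block gave 171, 2148 and 1874 probe sets, 35 TNF-induced genes with a median of -1.09, and 27 lower. Under the block, feedback inhibitors (0.37) and epithelial markers (0.13) were no longer called in E2 and TNF against untreated, and the block changed no other list call.

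Leaving out each array in turn gave 121 to 179, 1631 to 1964 and 1326 to 1877 probe sets, 29 to 38 TNF-induced genes, 20 to 26 lower, medians from -1.33 to -1.07, and 8 to 10, 6 to 8 and 6 to 9 lists. List medians ran from -0.11 to -0.057 (sterol) and 0.12 to 0.53 (endothelial) in TNF against untreated, from 0.18 to 0.21 (immediate early) and -0.40 to -0.26 (matrix) in E2 and TNF against TNF, and from 0.20 to 0.43 (feedback), 0.085 to 0.17 (epithelial) and -0.12 to -0.076 (mitochondrial) in E2 and TNF against untreated. In TNF against untreated camera gained sterol genes without TNF replicate 2 (adjusted p = 0.0384) or 4 (0.0253). It gained endothelial markers without TNF replicate 2 (0.0447) or 4 (0.0365) or untreated replicate 2 (0.0396). In E2 and TNF against untreated it gained mitochondrial genes without E2 and TNF replicate 3 (0.0438) or untreated replicate 2 (0.0288). In E2 and TNF against TNF, SOCS1 (1.17) ran from -0.35 to 1.36, turning to -0.35 and -0.30 without E2 and TNF replicates 1 and 2, and CDC25A (1.39) from -0.040 to 1.53, turning without replicate 3, because another probe set then stood for the gene. Of 12768 values of named genes under alternatives, 11944 kept direction and side of the threshold, 740 fell below it and 81 rose past it. Dim genes are limited by signal over background, as the pseudocount understates their changes.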

Other observations

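No test in this part was chosen after its result was seen, and the lists were fixed before. Of 24 heat shock and unfolded protein response genes, 2 rose and 2 fell between TNF and E2 and TNF arrays (3 and 3 adjusted over the list alone; camera adjusted p = 0.646). The co-chaperone gene BAG3 rose by 0.53 ± 0.08, and TRIB3, a pseudokinase induced by stress, changed by -1.05 ± 0.08 and the chaperone HSP90AA1 by -0.38 ± 0.08. DNAJB1 also rose (0.30 ± 0.09), a call lost without TNF replicate 1, 2 or 3 or E2 and TNF replicate 1, 2 or 3 (adjusted p from 0.0520 to 0.0990). None of 25 mitochondrial and oxidative phosphorylation genes passed in that contrast (0 and 0 adjusted over the list alone; camera adjusted p = 0.228), and neither did any of 21 apoptosis and survival regulators (0 and 0 adjusted over the list alone; camera adjusted p = 0.337).

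Interferon response genes gave 4 higher and 1 lower of 27 in E2 and TNF against TNF (5 and 3 adjusted over the list alone; camera adjusted p = 0.217, fry adjusted p = 0.00221), with ISG20, an exonuclease gene, at 2.31 ± 0.12, OASL at 1.17 ± 0.13 and IFI44 at 0.53 ± 0.11. IFIT3 (0.64 ± 0.18) was lost without TNF replicate 1 or 2 or E2 and TNF replicate 2 or 3 (adjusted p from 0.0611 to 0.108), and the lower gene, IRF1 (-0.31 ± 0.09), without TNF replicate 1 or 3 or E2 and TNF replicate 1, 2 or 3 (adjusted p from 0.0529 to 0.109). TIMP3, an inhibitor of matrix proteases, rose by 1.90 ± 0.15 while MMP13 and MMP7 fell. The median and mean of a list differed in sign for heat shock genes in TNF against untreated (0.0049 and -0.05, tested lower), endothelial markers in E2 and TNF against TNF (-0.05 and 0.09, tested higher) and matrix proteases in E2 and TNF against untreated (-0.03 and 0.33, tested higher). With each array left out in turn, the median ran from -0.016 to 0.043 for the heat shock genes and from -0.23 to 0.017 for the endothelial markers. The sign of both therefore rests on single arrays. That of matrix proteases ran from -0.064 to -0.0023. Camera at the preset correlation called none of these lists. For matrix proteases fry did (adjusted p = 6.19e-04), as did camera with a stricter signal filter, at 50% of the trimmed mean (adjusted p = 0.0464).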
